A study of Mus musculus with 4514 samples.

How the data were processed

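The series covers mouse hepatocytes, the main cell type of the liver, and holds 4514 samples that the labels place in 38 groups. Nearly every sample is a single cell or a single nucleus. Hepatocytes came from mice carrying Alb-Cre, a recombinase active in hepatocytes, and a Rosa-tdTomato reporter, per the labels. Cells from 12 ages and P60 cells sorted by DNA content (2N, 4N, 8N) were processed with mSTRT-seq, a method that tags each transcript end in wells, pools the barcoded cDNA and then builds 1 library from the pool. Nuclei at P0, P9, P18 and P60 were released by homogenising sorted hepatocytes, stained for DNA, sorted and processed with the same chemistry and 4 + 16 amplification cycles. Wild-type cells and cells labelled as knockouts of Nr2f2, Usf1, Xbp1 or Tef were processed with Smart-seq3, which reads along the transcript and gives each cell its own library. The last 6 samples are poly(A) RNA-seq libraries of sorted cell populations at P60, prepared with a directional kit.

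The deposited values are whole-number counts per gene symbol, with no normalization, in 1 table for each assay. Each table holds 40824 genes and 92 ERCC spike-in entries. Spike-ins took 1.327% of all counts in the mSTRT-seq cells and 4.339% in the nuclei, with 0 counts in the Smart-seq3 cells and the bulk libraries, and they were left out of library sizes and tests. The submitters' processing notes name Bowtie2, TopHat, TopHat2 2.1.0, HISAT2 2.1.0, Trimmomatic 0.39, UMI-tools 0.5.0, SAMtools 1.3.1, HTSeq 0.6.0 and featureCounts 1.5.3 and 2.0.0 without a role or an order, and name the builds GRCm38 and mm10. Which counter made which table, whether strand was used and how reads shared by similar genes were counted are not given in the sources used here. Values of gene families with near-identical members (Mup, Cyp2c, Cyp2a, Cyp3a, Saa) and of antisense or overlapping genes are therefore uncertain as to the member. Whether the counts are reads or molecules is also not given for each table. Among genes seen in 1 to 5% of cells, 57.4% of the values above 0 were a count of 1 in the mSTRT-seq cells (90th percentile 4), 48.0% in the nuclei (90th percentile 22) and 33.1% in the Smart-seq3 cells (90th percentile 8). Counts that are amplified reads are not independent molecules, so all intervals and detection limits given here cover counting error only. Of the mitochondrial genome list, 0 genes were measured in any comparison. Gene coordinates were taken from GENCODE release M21 on GRCm38.

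No label names an animal, litter or culture. The cells of a group were therefore summed into 1 pool, and pools or bulk libraries, never cells, were the replicates. The p-values measure only the spread between these pools or libraries, which may be technical. Of the 174 unsorted P60 cells, 58 were used, taken at even steps of label number, because their column names begin like those of the ploidy-sorted P60 cells and had to be listed 1 by 1, and 116 columns were not used. In all, 2053 mSTRT-seq cells, 1113 nuclei and 1226 Smart-seq3 cells were summed. The pools from E17.5 to P60, in order of age, held 89, 172, 116, 172, 131, 148, 150, 153, 199, 178, 135 and 58 cells, and the 2N, 4N and 8N pools at P60 held 125, 144 and 83 cells. The 2N nuclei pools at P0, P9, P18 and P60 held 107, 75, 103 and 340 nuclei, the 4N pools 12, 21, 46 and 161, and the 1x2N, 2x2N, 1x4N and 2x4N pools 57, 66, 69 and 56. At P12+40d, the WT, Nr2f2-KO, Usf1-KO, Xbp1-KO and Tef-KO pools held 164, 165, 63, 207 and 126 cells, and at P60+14d the WT, Nr2f2-KO and Usf1-KO pools 184, 161 and 156. No doublet caller was run, because each sample is a separately picked or sorted cell or nucleus.

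The design, the groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The main test was edgeR's two-sided quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM normalization and filterByExpr, and Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05. The 12 age pools were compared in 3 windows of 4 ages each, early (E17.5, E19.5, P0, P3), middle (P6, P9, P12, P15) and late (P18, P24, P30, P60), in 1 model with 9 residual degrees of freedom. Change within a window is part of the spread in that model. The 4N and 2N nuclei were compared over 4 ages with age as a block (3 residual degrees of freedom). Nr2f2-KO and Usf1-KO pools were compared with WT over 2 stages with stage as a block (6 pools, 2 residual degrees of freedom). The 6 bulk libraries were fitted together (3 residual degrees of freedom). Genes tested numbered 12888 in cells, 13025 in nuclei, 16183 in the knockout pools and 10984 in bulk, and the common biological coefficients of variation were 0.389, 0.716, 0.396 and 0.094. Fold changes are log2 with standard errors (SE), and levels in the tested comparisons are CPM, counts scaled to TMM-adjusted library size, computed here from the deposited counts. Levels and folds of single pools (the untested pairs, the knockout targets by pool, the course of Usf1 and the search for a pool far from the others) are CPM of the pool's total count without TMM.

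Lists of genes were fixed for fetal liver genes, cell cycle, drug-metabolising enzymes, urea cycle, gluconeogenesis and glycolysis, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, bile acids, plasma proteins, the unfolded protein response, ATF4 stress, the circadian clock, p53 targets, the growth hormone axis, female-biased and male-biased genes, pericentral and periportal genes, hepatocyte transcription factors, interferon response, acute phase, dissociation genes, ribosomal proteins and the mitochondrial genome. Marker lists covered erythroid, endothelial, macrophage, stellate, cholangiocyte, and lymphocyte and neutrophil cells. Some lists overlap: 7 of the 27 drug-metabolising enzymes are also in the pericentral list, 5 of the 10 urea cycle genes and 4 of the 15 gluconeogenesis and glycolysis genes are in the periportal list, and 1 cholangiocyte marker, Spp1, is in the periportal list. In the unsorted P60 cell pool, 2 of 15 endothelial, 0 of 15 macrophage, 2 of 15 stellate, 7 of 14 cholangiocyte, 7 of 14 erythroid and 0 of 16 lymphocyte and neutrophil markers reached 1 CPM. Lists were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 267 tests run. No list call held with an estimated correlation, where the lowest camera adjusted p was 0.196. That value was reached even where every measured periportal gene was called lower in CV than PV. Missing the threshold in this setting therefore does not show that a list is unchanged.

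Groups with 1 pool each (P60 cell ploidy, nuclei by number of nuclei per cell, Xbp1-KO, Tef-KO, and each knockout at 1 stage) were not tested. For these, both levels, the fold with an exact 95% counting interval and the percentile of a list's median among 10000 random lists matched on mean expression are given as descriptions. The list medians used genes with a mean of at least 1 CPM and a pseudocount of 1 CPM. A fold against a pool with no count was computed against 3 counts per pool and is written as at least that fold. The comparisons of 4N with 2N and 8N with 4N cells, of 1x4N with 2x2N nuclei and of each knockout at each stage were added after the data were seen, as was the choice of the list that stands for each untested comparison.

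Named genes followed a fixed rule. In tested comparisons these were the 10 genes with the largest fold in each direction among those with an adjusted p under 0.05, a mean of at least 20 CPM and non-overlapping pools (the same sign in every pair in blocked designs), without predicted gene models and pseudogenes. In untested pairs these were the 10 per direction with the largest fold by the interval bound nearest 1, among genes at least 2-fold apart and counted in at least 10% of the cells of the higher pool. The 4 knockout targets, the bulk sort markers Cdh1 and Nt5e and up to 4 members of each list were always eligible. Which of the eligible genes the text prints was chosen after their values were seen.

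Zonation within an age was measured as Spearman's correlation over cells between the summed counts of 30 pericentral and 28 periportal genes, in cells thinned to 97200 counts, leaving out 170 shallower cells. The trend of that value with age order was tested over the 12 ages with two-sided permutation tests of 100000 permutations, and 200 pairs of random lists matched on expression gave the value without zonation.

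Alternatives were DESeq2 1.42.0 size factors and Wald test, no low-count filter, cells thinned to 1 depth (90900 counts for cells, 29800 for nuclei, 501800 for Smart-seq3 cells), cells without those in which markers of other cell types held over 1% of counts, other age models, other blocks, and leaving out each pool or library. A minimum of 1000 genes per cell (500 per nucleus) removed no cell, so a minimum of 5000 was added after the data were seen, as were the models without both embryonic pools, with the ploidy-sorted cells in place of the P60 pool, with only the P18 and P60 nuclei, and without Yam1 and RP23-8J15 models in bulk. Other software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

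The tests were run on simulated counts with the real mean of each gene, the real depths, 1 common spread for all genes and 200 changed genes. Real genes differ in spread, so the shares below describe the simulation only. In the data, 5112 genes were called late against early. Of these, 1574 higher and 1509 lower genes changed at least 2-fold, so many smaller changes were called too. For late against early ages (12665 genes) 3.1%, 78.8% and 100% of genes changed 2-, 4- and 8-fold were recovered. For middle against early (12683 genes) these shares were 14.3%, 89.2% and 100%, and for late against middle (12678 genes) 19.7%, 86.4% and 100%. For 4N against 2N nuclei (12595 genes) they were 0%, 0% and 9.4%, for Nr2f2-KO against WT (15712 genes) 1.5%, 22.7% and 76.9%, and for Usf1-KO against WT (15694 genes) 0%, 34.8% and 81.8%. In the simulation the nuclei and knockout models thus missed most changes of 4-fold or less. For CV against PV in bulk (10717 genes) 83.3%, 95.5% and 98.5% were recovered, and 21 of 203 calls were unchanged genes. For CV against ML (10720 genes) the shares were 77.6%, 97% and 100%, and for PV against ML (10719 genes) 84.8%, 100% and 100%.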

Results

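Gene expression was measured in single mouse hepatocytes and single hepatocyte nuclei from late gestation to adulthood, in hepatocytes labelled with knockouts of transcription factors, and in bulk populations sorted by surface markers. Unsorted cells came from 12 ages. The 12 pools and 3 ploidy-sorted pools held 2053 cells. The pools at E17.5, E19.5, P0, P3, P6 and P9 had total counts of 9490297, 30247801, 23254585, 25702986, 23083951 and 28605033. The pools at P12, P15, P18, P24, P30 and P60 had total counts of 26724520, 23600132, 35994359, 47527661, 28091891 and 11830970. The smallest pools were P60 (58 cells) and E17.5 (89 cells). At P60, cells were also sorted by DNA content into 2N (20197242 counts), 4N (24874880 counts) and 8N (15469538 counts from 83 cells).

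Nuclei, 1113 in all, were collected as 2N and 4N at 4 ages. The 2N pools at P0, P9, P18 and P60 held 9071799, 8523399, 13979287 and 40967901 counts. The 4N pools held 1628926, 3012379, 7454468 and 29460527 counts, those at P0, P9 and P18 from only 12, 21 and 46 nuclei. P60 nuclei were also sorted by the number and DNA content of the nuclei of a cell: 1x2N (57 nuclei, 7073207 counts), 2x2N (66 nuclei, 12193695 counts), 1x4N (69 nuclei, 21195886 counts) and 2x4N (56 nuclei, 18022186 counts). The knockout series held 1226 cells. At the stage labelled P12+40d, the WT, Nr2f2-KO, Usf1-KO, Xbp1-KO and Tef-KO pools held 137925496, 130134724, 54530774, 161678052 and 102549164 counts, and the Usf1-KO pool was the smallest (63 cells). At the stage labelled P60+14d, the WT, Nr2f2-KO and Usf1-KO pools held 137580291, 126776724 and 124425503 counts. The bulk libraries held 13889655 and 22729462 counts (PV), 18143472 and 16049840 (ML) and 13144208 and 14596435 (CV).

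Ages were compared to follow the course of hepatocyte maturation. Fetal liver genes fell from the early to the late window. Afp, the fetal serum carrier protein, fell from 18360 ± 5915 to 41.7 ± 40.95 CPM (mean ± SD, n = 4 pools each; log2 -8.78 ± 1.32 SE, edgeR adjusted p = 0.00066). Igf2, an imprinted fetal growth factor, fell from 1674 ± 588 to 6.05 ± 8.59 CPM (log2 -8.09 ± 1.19, edgeR adjusted p = 0.000599, n = 4 pools each). Its imprinted neighbour H19 fell 21.2-fold (log2 -4.41 ± 1.32) and Dlk1, an imprinted Notch ligand, 1109-fold (log2 -10.12 ± 1.66). All 11 measured fetal liver genes were called lower, and 11 adjusted over the list alone, with a median log2 of -5.81 (camera adjusted p = 3.68e-07, but adjusted p = 0.484 with an estimated correlation). Other genes with the largest falls were Slc36a2, an amino acid transporter (log2 -10.47 ± 1.62), Ggt1, a glutathione-cleaving enzyme (log2 -10.23 ± 1.46), Rbp2 (log2 -9.78 ± 1.42), the protease inhibitor A2m (log2 -9.0 ± 1.63) and Bex1 (log2 -8.21 ± 0.92), with edgeR adjusted p values between 0.000306 and 0.0015.

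Over the same interval 16 of 27 drug-metabolising, 10 of 17 bile acid and 17 of 30 pericentral genes rose, and none of these 3 list calls held with an estimated correlation (adjusted p = 0.484, 0.494 and 0.494). Cyp2c29 rose from 3.85 ± 4.76 to 1271 ± 341 CPM (log2 8.33 ± 1.53, edgeR adjusted p = 0.00162, n = 4 pools each) and Cyp2e1, which oxidises ethanol, from 680 ± 766 to 3611 ± 459 CPM (log2 2.41 ± 0.84, edgeR adjusted p = 0.0394, n = 4 pools each). Of the drug-metabolising enzymes, 0 fell (17 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.79e-06, but adjusted p = 0.484 with an estimated correlation). Aldh1a1, a retinaldehyde dehydrogenase, rose 316.3-fold (log2 8.31 ± 1.19), Mfsd2a, a lipid transporter, 532-fold (log2 9.06 ± 1.74) and the protease inhibitor Mug2 322.9-fold (log2 8.34 ± 1.26). The urinary proteins Mup3 (595.5-fold, log2 9.22 ± 1.80) and Mup20 (371.7-fold, log2 8.54 ± 1.78) rose too, and which member of this family of near-identical genes was counted is uncertain. Of 17 bile acid genes, 10 rose and 0 fell, among them the conjugating enzyme Slc27a5 (log2 2.28 ± 0.33) and the bile salt pump Abcb11 (log2 1.54 ± 0.22), with camera adjusted p = 4.95e-05, but adjusted p = 0.494 with an estimated correlation. Of 30 pericentral genes, 17 rose and 2 fell (17 and 4 adjusted over the list alone; camera adjusted p = 9.68e-05, but adjusted p = 0.494 with an estimated correlation). Of 28 periportal genes, 12 rose and 2 fell (camera adjusted p = 0.00565, but adjusted p = 0.688 with an estimated correlation), with Cdh1 lower (log2 -1.62 ± 0.22) and Uroc1, an enzyme of histidine breakdown, higher (log2 1.40 ± 0.19).

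Of 28 transcription factors, 16 rose and 2 fell (16 and 3 adjusted over the list alone; camera adjusted p = 9.26e-05, but adjusted p = 0.374 with an estimated correlation). Zbtb20, a repressor of Afp, rose 4.63-fold (log2 2.21 ± 0.34). Tef, a clock output factor, rose from 13.5 ± 5.64 to 64.7 ± 13.7 CPM (log2 2.26 ± 0.28) and Nr2f2, a nuclear receptor, from 7.45 ± 4.95 to 22.8 ± 9.38 CPM (log2 1.59 ± 0.45). The edgeR adjusted p values of these 3 were 0.000701, 0.000382 and 0.0155. Usf1 (log2 0.30 ± 0.73, edgeR adjusted p = 0.776) and Xbp1 (log2 -0.60 ± 0.26, edgeR adjusted p = 0.0832) did not pass. Of 84 ribosomal protein genes, 81 fell and 0 rose (82 adjusted over the list alone; median log2 -1.16, camera adjusted p = 1.21e-22, but adjusted p = 0.494 with an estimated correlation), for example Rps6 from 1087 to 453 CPM (log2 -1.26 ± 0.17). Of 18 clock genes, 8 rose and 0 fell (camera adjusted p = 0.0133, but adjusted p = 0.494 with an estimated correlation), including Usp2, which rose 35.3-fold. Of 29 cell cycle genes, 4 fell and 0 rose (1 adjusted over the list alone; camera adjusted p = 0.0242, but adjusted p = 0.821 with an estimated correlation). Of 15 male-biased genes, 9 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 0.00623, but adjusted p = 0.642 with an estimated correlation), and 4 of 10 female-biased genes rose (camera adjusted p = 0.556). Xist, transcribed from the inactive X chromosome, had counts in 65.2% of E17.5 cells and 71.5% of E19.5 cells and in no more than 1.7% of the cells of any other age pool. The male-biased gene Ddx3y stood at 20.44 CPM at E17.5 and 14.02 CPM at E19.5, and at 52.06 to 74.93 CPM at the other ages (pool totals, without TMM). Sex therefore differs between the embryonic and the later pools. It cannot be told apart from age in comparisons with the early window.

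The remaining lists did not pass in camera between late and early ages. Plasma proteins held 3 called higher and 8 lower of 26 (camera adjusted p = 0.148): Apoc3 rose 12.2-fold, Fgg, a fibrinogen chain, fell from 10340 ± 2130 to 4055 ± 312.8 CPM (log2 -1.35 ± 0.20), and Alb stood at 26280 and 20160 CPM (log2 -0.38 ± 0.19, edgeR adjusted p = 0.138). The other metabolic lists held, as higher and lower calls, 2 and 1 of 10 urea cycle genes (camera adjusted p = 0.193), and 3 and 3 of 14 gluconeogenesis and glycolysis genes (0.348). The lipid lists held 4 and 1 of 12 fatty acid synthesis genes (0.182), 0 and 1 of 18 cholesterol synthesis genes (0.129) and 0 and 5 of 20 fatty acid oxidation genes (0.376). Among these, the fructose kinase Khk rose 7.55-fold, the lipogenic regulator Thrsp 92.9-fold and the urea cycle enzyme Otc 2.78-fold, and Hadhb of the mitochondrial trifunctional protein fell 2.38-fold. The stress and signalling lists held 3 and 5 of 20 unfolded protein response genes (camera adjusted p = 0.543), 1 and 4 of 13 ATF4 genes (0.0941), and 2 and 5 of 14 p53 targets (0.599). As higher and lower calls, they also held 6 and 2 of 12 growth hormone genes (0.399), 1 and 0 of 13 interferon genes (0.313, with a median log2 of -0.03 and a mean of 0.25), 4 and 2 of 14 acute phase genes (0.277) and 3 and 6 of 14 dissociation genes (0.306). The amino acid enzymes Asns (44.4-fold) and Psat1 (177.8-fold) fell, the growth hormone receptor Ghr rose 3.34-fold and the insulin-like growth factor binding protein Igfbp1 fell 5.96-fold. Markers of other cells held 0 and 1 of 9 erythroid (0.237), 3 and 3 of 8 endothelial (0.656, direction down although the median was 0.46), and 0 and 1 of 14 macrophage genes (0.855). They held 2 and 0 of 9 stellate (0.323), 1 and 2 of 7 cholangiocyte (0.527) and 0 and 3 of 6 lymphocyte and neutrophil genes (0.391). The neutrophil gene S100a8 stood at 107.6 ± 200 CPM early and 0.443 CPM late (log2 -7.99 ± 1.93, edgeR adjusted p = 0.00689, n = 4 pools each), and the early level lay mostly in the E17.5 pool. In all, 2573 genes were called higher and 2539 lower of 12888 (edgeR quasi-likelihood, Benjamini-Hochberg), of which 1574 and 1509 changed at least 2-fold.

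**Figure D1:**
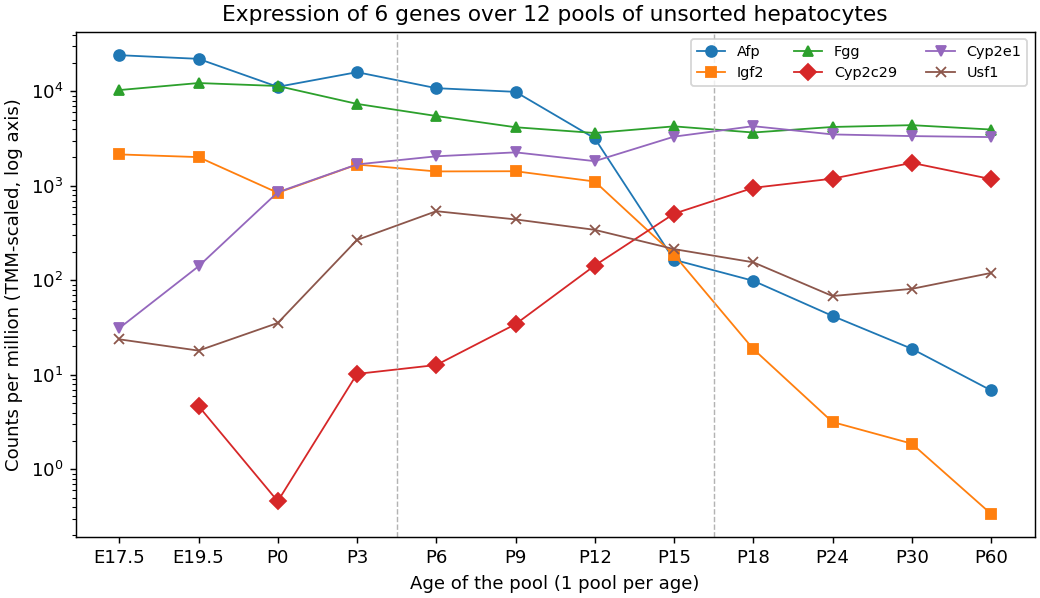
Levels of 6 genes (CPM, log axis) against age in 12 pools of unsorted hepatocytes, 1 point per pool, with dashed lines between the early, middle and late windows. Afp and Igf2 fall to means of 41.7 and 6.05 CPM in the late window while Cyp2c29 and Cyp2e1 rise to 1271 and 3611 CPM, and the value of 0 for Cyp2c29 at E17.5 is not drawn.

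Between the early and middle windows, 74 of 84 ribosomal protein genes and 9 of 20 unfolded protein response genes fell, and 9 of 30 pericentral genes rose. The organic anion transporter Slc22a7 rose from 0.958 ± 1.82 to 115.8 ± 84.2 CPM (log2 6.79 ± 1.23, edgeR adjusted p = 0.0119, n = 4 pools each) and Tdo2, which degrades tryptophan, 25.9-fold (log2 4.70 ± 1.01). Dio1, which activates thyroid hormone, rose 16.6-fold (log2 4.06 ± 1.11) and the growth factor Igf1 9.05-fold (log2 3.18 ± 0.86). Tff3, a trefoil peptide, fell from 1727 ± 829 to 34.9 ± 27.6 CPM (log2 -5.63 ± 0.63, edgeR adjusted p = 0.00508, n = 4 pools each). Slc36a2 (985-fold), Dlk1 and Tmsb10 (172.3-fold) and Acot1 (48.5-fold) fell with it, and Afp did not pass (log2 -1.61 ± 0.96, edgeR adjusted p = 0.277).

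Of 20 unfolded protein response genes, 9 fell and 0 rose (camera adjusted p = 1.55e-05, but adjusted p = 0.484 with an estimated correlation). Among them were the chaperones Hspa5 (log2 -1.03 ± 0.21), Hsp90b1 (log2 -0.87 ± 0.16) and Dnajb9 (log2 -1.10 ± 0.19). Xbp1, a regulator of this response, fell 1.92-fold (log2 -0.94 ± 0.26, edgeR adjusted p = 0.0347, n = 4 pools each). Cholesterol synthesis genes had a median log2 of -2.11 (2 of 18 lower, 10 adjusted over the list alone; camera adjusted p = 1.11e-05, but adjusted p = 0.613 with an estimated correlation), with Lss down 9.98-fold and Insig1 4.53-fold. Of 84 ribosomal protein genes, 74 fell (81 adjusted over the list alone; camera adjusted p = 2.34e-33, but adjusted p = 0.484 with an estimated correlation). Cell cycle genes had a median log2 of 1.39 (2 of 29 higher, 2 adjusted over the list alone; camera adjusted p = 9.75e-06, but adjusted p = 0.653 with an estimated correlation), the calls being Tyms and Pcna of DNA synthesis (2.07- and 1.99-fold). Of 30 pericentral genes, 9 rose (median log2 1.24; camera adjusted p = 2.59e-08, but adjusted p = 0.441 with an estimated correlation), including the Wnt target Lgr5 (5.02-fold). Growth hormone genes (5 of 12 higher, camera adjusted p = 0.0329, but adjusted p = 0.548 with an estimated correlation) included Stat5b (2.24-fold). Erythroid (camera adjusted p = 0.0451, median log2 -1.72), macrophage (0.0341, 1.14) and stellate markers (0.042, 1.56) passed in the same interval, with adjusted p values of 0.553, 0.777 and 0.682 with an estimated correlation. Usf1 stood at 86.3 ± 121.3 CPM early and 384.8 ± 139.2 CPM in the middle window (log2 2.16 ± 0.76, edgeR adjusted p = 0.0791, n = 4 pools each).

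In all, 818 genes were called higher and 895 lower in the middle than the early window (edgeR quasi-likelihood, Benjamini-Hochberg). These calls were 13.3% of the 12888 genes tested, and 21.3% with DESeq2. The share rested on single pools: it was 1.62% without P12, 3.75% without P15, 4.64% without E19.5, 5.14% without P9, 5.37% without E17.5, 23.4% without P3 and 0.0621% without both embryonic pools.

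From the middle to the late window, 5 of 11 fetal liver genes fell and 0 rose (8 adjusted over the list alone; median log2 -3.37, camera adjusted p = 3.75e-06, but adjusted p = 0.494 with an estimated correlation). Igf2 fell from 1038 ± 587 to 6.05 ± 8.59 CPM (log2 -7.40 ± 1.15, edgeR adjusted p = 0.00824, n = 4 pools each) and Afp 143.9-fold (log2 -7.17 ± 1.23). Gpc3, a fetal cell surface proteoglycan, fell 23.1-fold (log2 -4.53 ± 1.20) and the fatty acid binding protein Fabp5 23.7-fold (log2 -4.57 ± 0.79). Mup3 rose 151.6-fold (log2 7.24 ± 1.65), Orm1, an acute phase plasma protein, 113.6-fold (log2 6.83 ± 1.47) and Pigr, the receptor that carries IgA into bile, from 6.10 to 360 ± 338.6 CPM (log2 5.88 ± 0.94). Of 29 cell cycle genes, 8 fell and 0 rose (24 adjusted over the list alone; median log2 -2.02, camera adjusted p = 2.97e-15, but adjusted p = 0.494 with an estimated correlation), including the replication factor Mcm2 (4.37-fold), Tyms (2.54-fold) and Hmgb2 (3.87-fold).

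Fatty acid synthesis genes had a median log2 of 2.02 (3 of 12 higher and 1 lower, 9 and 1 adjusted over the list alone; camera adjusted p = 0.00202, but adjusted p = 0.601 with an estimated correlation). The desaturase Scd1 stood at 14.5 CPM in the middle and 1215 ± 1423 CPM in the late window (log2 6.39 ± 1.82, edgeR adjusted p = 0.0417, n = 4 pools each) and Me1 up 6.0-fold. Of 20 unfolded protein response genes, 5 rose (8 adjusted over the list alone; camera adjusted p = 0.00167, but adjusted p = 0.548 with an estimated correlation), among them Syvn1 (1.98-fold) and Dnajb9 (1.96-fold). Drug-metabolising enzymes (7 of 27 higher, camera adjusted p = 0.000132, but adjusted p = 0.494 with an estimated correlation) included Gstm1 (4.1-fold), and bile acid genes (6 of 17 higher, 9 adjusted over the list alone; camera adjusted p = 0.00218, but adjusted p = 0.606 with an estimated correlation) included Baat (5.01-fold). The secreted proteins Trf and Ahsg fell 2.2-fold and 2.15-fold. Pericentral genes (4 higher and 2 lower of 30, camera adjusted p = 0.606) and periportal genes (4 and 2 of 28, camera adjusted p = 0.0514) did not pass. Cdh1, which encodes an adhesion protein, fell 2.98-fold, and Tef rose 2.83-fold.

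In all, 773 genes were called higher and 798 lower in the late than the middle window (edgeR quasi-likelihood, Benjamini-Hochberg). These were 12.2% of the 12888 genes, and 20.5% with DESeq2. Here too the share depended on single pools, with 3.24% without P9, 3.65% without P30, 4.19% without P6, 4.87% without P12, 5.63% without P24 and 5.94% without P60.

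Zonation, the division of labour between hepatocytes near the portal and the central vein, was followed over cells of 1 age as the correlation of pericentral with periportal counts. Spearman's rho over thinned cells was -0.308, -0.227 and -0.235 at E17.5, E19.5 and P0, where 27, 22 and 26 of 200 random list pairs were as low. It was -0.617 at P3 (1 of 200 random pairs as low) and then -0.763, -0.81, -0.839, -0.885, -0.763, -0.804, -0.903 and -0.929 from P6 to P60 (0 of 200 at each age). The value fell with age order over the 12 ages (Pearson's r -0.859, p = 0.00013; Spearman's rho -0.846, p = 0.00088, two-sided permutation tests; r -0.816 without the first and last age). It was computed under 5 settings as 1 relation, without adjustment over the settings. Trends of single genes with age were fitted only as alternative models. The share of thinned cells with a count of Cyp2f2, a periportal cytochrome P450, was 47.2% at E17.5, 20.9% at P0 and 90.7% at P60, while 98.1% of cells at E17.5 and 72.2% at P60 had a count of Glul, the pericentral glutamine synthetase. Without thinning the trend was weaker (r -0.686, permutation p = 0.0151, n = 12 ages), and rho was above 0 at every age from E17.5 to P6, ranging from 0.184 to 0.514, and between -0.503 and 0.032 from P9 to P60.

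**Figure D2:**
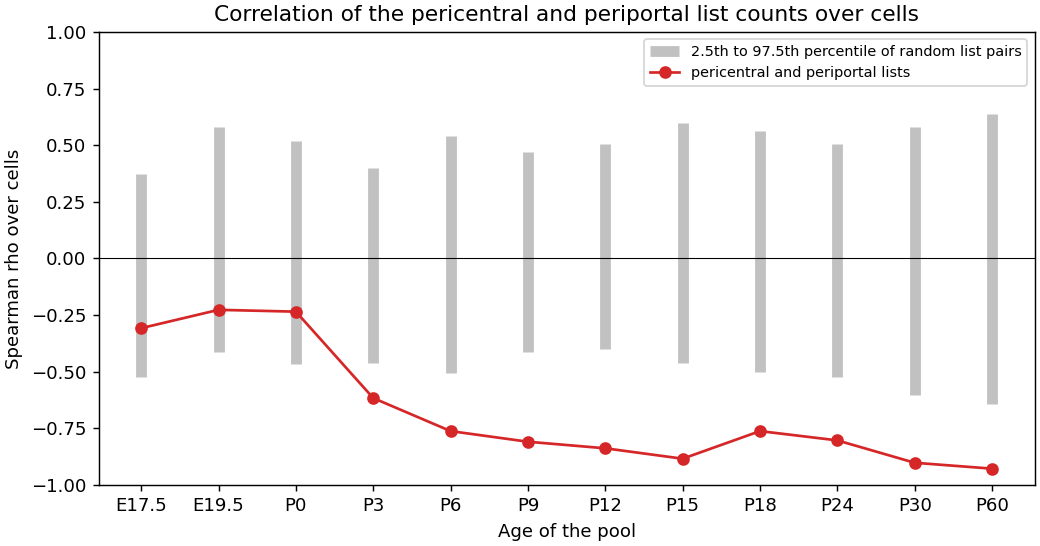
Spearman's rho over thinned cells between summed pericentral and periportal counts (vertical axis, no unit) at each of 12 ages, 1 point per age, with the middle 95% of 200 matched random list pairs. The value moves from -0.308 at E17.5 to -0.929 at P60 and lies below that band from P3 on.

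P60 cells were sorted by DNA content to look at differences between ploidy classes. With 1 pool per class there was no replicate check and no test, and levels are CPM of the pool's total, without TMM. Pericentral genes were higher in 8N than in 2N cells: all 27 measured members, with a median log2 of 1.75 (counting interval 1.66 to 1.86), against -0.18 to 0.17 in the middle 95% of random lists (100th percentile). Cyp2e1 stood at 3259 CPM in 8N and 550 CPM in 2N cells, 5.92-fold (95% counting interval 5.80 to 6.05), and the glutamate transporter Slc1a2, with 1933 and 24 counts, differed 105.2-fold (70.5 to 164.5), with 41.6% of its 8N counts in 1 cell. Periportal genes were lower, with 2 of 28 members higher and a median log2 of -0.88 (percentile 0), including Hal of histidine breakdown (0.55-fold) and the serine dehydratase Sds (0.38-fold). Male-biased genes were higher (14 of 16 members, median log2 1.83, percentile 100), led by the fatty acid elongase Elovl3 at 153.9 against 7.43 CPM (20.7-fold, 17.6 to 24.6). So were 19 of 20 unfolded protein response genes (median log2 0.67, percentile 100) and 13 of 18 cholesterol synthesis genes (median log2 0.63, percentile 100). Of 6 female-biased genes, 2 were higher (median log2 -1.76, percentile 0). Of 24 cell cycle genes, many reaching 1 CPM only through 8N cells, 16 were higher (median log2 1.58). For Ect2 (104.4-fold, 18.2 to 4176), 56.2% of counts came from 1 cell. The cholangiocyte and periportal marker Spp1 stood at 3.69 CPM in 8N and 31.1 CPM in 2N cells.

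In the pericentral and periportal lists the 4N pool lay on the same side of the 2N pool as the 8N pool did, and both comparisons used the same 2N pool. In 4N against 2N cells, all 27 pericentral and 2 of 28 periportal genes were higher (median log2 1.70 and -0.57). Only 10 cell cycle genes were measured there, 2 of them higher (median log2 -0.32, percentile 1.92), so the 8N and 4N sets cannot be compared. Erythroid markers had a median log2 of -1.76 in 8N and -1.68 in 4N against 2N cells (both at percentile 0), and the globin gene Hbb-bs stood at 18.8 CPM in 2N and 3.17 CPM in 8N cells. Between 8N and 4N cells the pericentral median was 0.07 (15 of 27 higher) and the periportal -0.17. Of 22 cell cycle genes, many reaching 1 CPM only through 8N, 19 were higher in 8N (median log2 1.70, percentile 100). Single cells held 85.9% of the 8N counts of Cdk1, 67% of Birc5 and 63.8% of Aurka. Spearman's rho of pericentral with periportal counts over thinned cells was -0.265 in the 2N, -0.802 in the 4N and -0.889 in the 8N pool, where 15, 1 and 0 of 200 random pairs were as low. Without thinning it was above 0 in all 3 pools (0.624, 0.089 and 0.281).

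Nuclei of 2N and 4N content were compared over 4 ages to follow their maturation. No gene passed in either direction among 13025 (0 calls in edgeR's quasi-likelihood test, 361 at an unadjusted p under 0.05, and 27 with DESeq2). Among cell cycle genes, Top2a stood at 105.5 ± 96.8 CPM in 4N and 4.52 ± 3.89 CPM in 2N nuclei (log2 3.80 ± 0.73, n = 4 pools each), Kif11 had a log2 of 3.60 ± 0.79 and Cenpf of 3.37 ± 0.86, all with an edgeR adjusted p of 1. The 29 cell cycle genes lay higher as a list (median log2 1.55, 6 calls adjusted over the list alone, camera adjusted p = 2.05e-16, but adjusted p = 0.441 with an estimated correlation). A sort by DNA content does not separate 4N nuclei from 2N nuclei that have copied their DNA before division. The cell cycle list therefore cannot tell a ploidy class from dividing nuclei. Plasma protein genes lay lower (median log2 -0.35; camera adjusted p = 4.88e-07, but adjusted p = 0.601 with an estimated correlation), with Hpx at 818 and 1197 CPM. So did periportal genes (median log2 -0.36; 0.0032, but adjusted p = 0.488 with an estimated correlation), with Hal at 155.6 and 272.1 CPM. Acute phase (median log2 -0.56, 1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00487, but adjusted p = 0.494 with an estimated correlation), growth hormone (-0.44; 0.00512, but adjusted p = 0.484) and ribosomal protein genes (-0.33; 0.0111, but adjusted p = 0.791) lay lower too. The median of all genes was -0.19. Pericentral genes had a median log2 of -0.20 (camera adjusted p = 0.768), and Cyp2e1 one of 0.80 ± 0.21 (1222 and 754 CPM). The count was 30 without a low-count filter, 29 without the P60 pair and 17 with only the P18 and P60 pairs.

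P60 nuclei from cells with 1 or 2 nuclei, 1 pool each, were not tested. Pericentral genes were higher in 2x2N than in 1x2N nuclei (15 of 22 members, median log2 0.48, counting interval 0.376 to 0.575, percentile 99.98) and in 2x4N than in 1x4N nuclei (15 of 23, median log2 0.37, 0.302 to 0.412, percentile 99.98). The first of these medians was 0.117 with every nucleus thinned to 1 depth. Several of the largest single-gene folds came from 1 nucleus, which held 98.5% of the counts of Retn (at least 251.6-fold higher in 2x2N), 95.7% of Xlr5a (758.5-fold lower) and 90.1% of Slc1a2 (0.0555 CPM in 2x4N and 55.2 CPM in 1x4N). Nuclei of the same cellular DNA content, 1x4N against 2x2N, differed in plasma protein genes (3 of 24 members higher, median log2 -0.28, percentile 0) and periportal genes (3 of 26, median log2 -0.37, percentile 0.01).

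Knockouts of Nr2f2, Usf1, Xbp1 and Tef were made to look at the functions of these factors in maturation. The target genes were not uniformly lower in the pools labelled as their knockouts. Nr2f2 (chromosome 7, 70351944 to 70366735, minus strand, GRCm38, protein coding) stood at 24.03 CPM (95% counting interval 23.2 to 24.9) in WT and 31.6 CPM (30.6 to 32.6) in Nr2f2-KO at P12+40d, and at 44.96 CPM (43.85 to 46.1) and 23.1 CPM (22.3 to 23.97) at P60+14d. Usf1 (chromosome 1, 171411313 to 171419142, plus strand) stood at 44.2 CPM (43.1 to 45.4) in WT and 30.1 CPM (28.7 to 31.6) in Usf1-KO at P12+40d, and at 68.6 CPM (67.2 to 70) and 116.6 CPM (114.7 to 118.5) at P60+14d. Xbp1 (chromosome 11, 5520659 to 5525893, plus strand) stood at 78.5 CPM (77.02 to 79.98) in WT and 81.5 CPM (80.1 to 82.9) in Xbp1-KO. Tef (chromosome 15, 81802421 to 81826863, plus strand) stood at 19.49 CPM (18.8 to 20.2) in WT and 44.1 CPM (42.8 to 45.4) in Tef-KO. Pools with other labels spanned as much: Nr2f2 was 8.03 CPM and Tef 5.72 CPM in Usf1-KO at P12+40d, Usf1 was 106.8 CPM in Nr2f2-KO at P60+14d and Xbp1 was 131.7 CPM in Usf1-KO at P12+40d. Counts over a whole gene do not show whether an edit removed part of it, so the directions below are those of the pools labelled with each knockout. These levels and those of single pools below are CPM of the pool's total, without TMM. With TMM, Usf1 stood at 36.2 CPM in Usf1-KO and 43.2 CPM in WT at P12+40d, and Nr2f2 at 9.67 CPM in Usf1-KO.

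**Figure D3:**
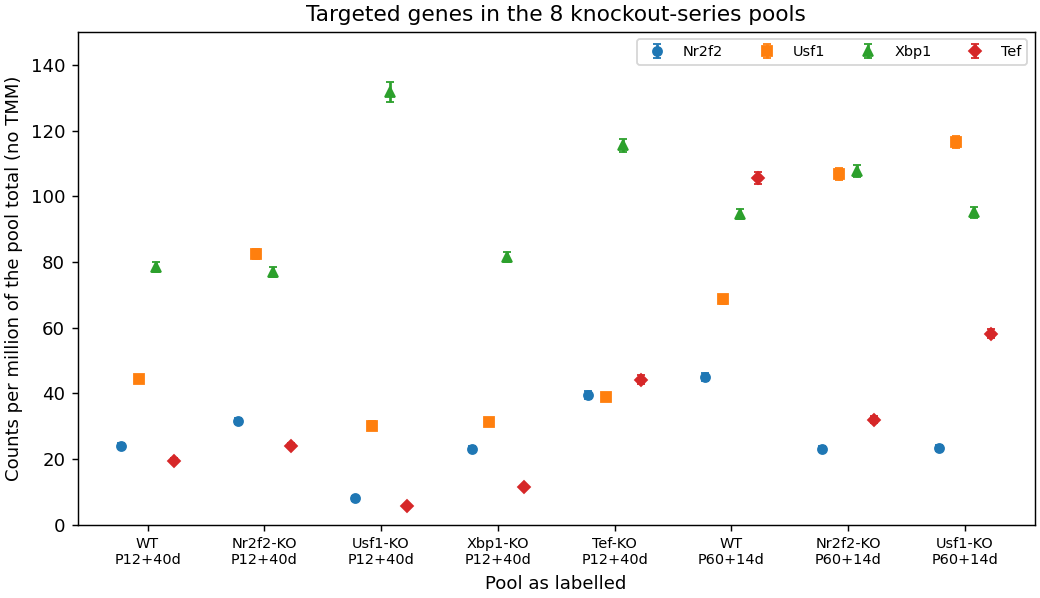
CPM of the pool total, without TMM, of Nr2f2, Usf1, Xbp1 and Tef in the 8 Smart-seq3 pools, with 95% exact counting intervals, on a linear axis from 0. Usf1 reaches 116.6 CPM in the pool labelled Usf1-KO at P60+14d against 68.6 CPM in WT, and Tef 44.1 CPM in the pool labelled Tef-KO against 19.49 CPM in WT.

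In the pools labelled Nr2f2-KO, pericentral genes lay lower and periportal genes higher than in WT as lists with a preset correlation (adjusted p = 0.484 and 0.494 with an estimated correlation), while no single gene passed. The pericentral share of counts was below that of WT in every knockout pool, whatever its target. At P12+40d it was 1.397% in WT and 0.741%, 0.46%, 1.07% and 1.022% in Nr2f2-KO, Usf1-KO, Xbp1-KO and Tef-KO. At P60+14d it was 2.105% in WT, 0.688% in Nr2f2-KO and 0.982% in Usf1-KO. A difference of the shared WT pools therefore cannot be told apart from an effect of 1 target. Cyp2e1 stood at 2538 ± 60.1 CPM against 6914 ± 2792 CPM in WT (log2 -1.37 ± 0.34, edgeR adjusted p = 0.922, n = 2 pools each), Cyp2c37 had a log2 of -1.39 ± 0.27 and Cyp2a5 of -2.16 ± 0.46. The lipogenic regulator Srebf1 stood at 51.8 and 160 CPM (log2 -1.48 ± 0.22, edgeR adjusted p = 0.546), the interferon-induced gene Rsad2 had a log2 of 4.16 ± 0.47 (0.509), the apolipoprotein gene Apoa4 of 2.06 ± 0.24 (0.509) and Nr2f2 of -0.20 ± 0.37 (0.993). Of 16183 genes, 0 passed in edgeR's quasi-likelihood test, 804 had an unadjusted p under 0.05 and 0.976% of the genes passed with DESeq2. In edgeR, 80 passed without Nr2f2-KO at P12+40d and 26 without Nr2f2-KO at P60+14d.

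As a list, pericentral genes had a median log2 of -0.89 (0 and 13 called adjusted over the list alone, higher and lower; camera adjusted p = 3.24e-25, but adjusted p = 0.484 with an estimated correlation) and periportal genes of 0.53 (7 and 0; 6.08e-13, but adjusted p = 0.494). Drug-metabolising enzymes (median log2 -0.52, 0 and 6; camera adjusted p = 3.47e-10, but adjusted p = 0.537 with an estimated correlation) and fatty acid synthesis genes (-0.71, 0 and 2; 4.25e-08, but adjusted p = 0.494) lay lower. Interferon genes (median log2 0.83, 2 and 0; camera adjusted p = 1.16e-09, but adjusted p = 0.494 with an estimated correlation), cell cycle genes (0.67; 7.47e-06, but adjusted p = 0.65) and acute phase genes (1.46; 0.00428, but adjusted p = 0.766) lay higher. The clock list had a median of -0.18 with a mean of 0.05 (0.0109, but adjusted p = 0.548). Saa1, an acute phase protein, reached 19860 ± 24050 CPM in the Nr2f2-KO and 4315 ± 5591 CPM in the WT pools (log2 5.37 ± 3.16, edgeR adjusted p = 0.98, n = 2 pools each). Endothelial markers had a median of -0.83 (camera adjusted p = 0.017, but adjusted p = 0.786 with an estimated correlation). The endothelial median turned to 0.446 without WT and 0.18 without Nr2f2-KO at P60+14d, the cell cycle median to -0.158 without Nr2f2-KO at P12+40d and the acute phase median to -0.898 without Nr2f2-KO at P60+14d. At P12+40d alone the median was -0.68 for pericentral, 0.77 for periportal and -0.23 for acute phase genes. At P60+14d alone these medians were -1.09, 0.25 and 1.94, and Saa2 differed 736-fold (counting interval 718 to 754).

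The pools labelled Usf1-KO shared their WT pools with the Nr2f2-KO pools, so like values in both are not independent. Usf1 itself had a log2 of 0.31 ± 0.31 (74.4 ± 54 and 53.7 ± 14.8 CPM, edgeR adjusted p = 0.914, n = 2 pools each). Srebf1 stood at 35.3 against 160 CPM (log2 -2.10 ± 0.22, edgeR adjusted p = 0.49, n = 2 pools each). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 31.2 against 134.2 CPM (log2 -2.01 ± 0.36) and Cyp2e1 at 2928 ± 1195 against 6914 ± 2792 CPM (log2 -1.24 ± 0.34), and none of these 3 genes passed. Of 16183 genes, 0 passed in edgeR's quasi-likelihood test, 823 had an unadjusted p under 0.05 and 1.02% of the genes passed with DESeq2. In edgeR, 25 passed without Nr2f2-KO at P12+40d and 26 without Nr2f2-KO at P60+14d.

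Pericentral genes had a median log2 of -0.99 (0 and 13 called adjusted over the list alone, higher and lower; camera adjusted p = 1.95e-21, but adjusted p = 0.488 with an estimated correlation), and drug-metabolising enzymes of -0.67 (0 and 9; 3.56e-13, but adjusted p = 0.494). Fatty acid synthesis genes (median log2 -0.72, 0 and 1; 1.57e-07, but adjusted p = 0.494) and female-biased genes (-2.17, 0 and 3; 8.04e-07, but adjusted p = 0.435) lay lower too. Periportal genes (median log2 0.52, 3 and 0; camera adjusted p = 2.74e-09, but adjusted p = 0.494 with an estimated correlation), interferon genes (0.66, 1 and 0; 9.76e-10, but adjusted p = 0.494) and acute phase genes (1.80; 5.56e-06, but adjusted p = 0.642) lay higher. Without Usf1-KO at P12+40d the acute phase median was -0.469. Beside these groups, cholangiocyte markers had a median of 1.76 (4 and 0; camera adjusted p = 6.63e-07, but adjusted p = 0.441 with an estimated correlation) and macrophage markers of 1.26 (0.000432, but adjusted p = 0.676). Lyz2 had a log2 of 3.30 ± 1.01 and Sox9 of 2.80 ± 0.68. Fetal genes had a median of 0.29 and a mean of -1.69 (camera adjusted p = 0.937). Acute phase genes took 22.7% of all counts in Usf1-KO at P12+40d and 8.67% in Nr2f2-KO at P60+14d, against 2.28% and 0.673% in WT at P12+40d and P60+14d.

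Across 16183 genes, the log2 folds of the Nr2f2-KO pools at the 2 stages, which share no pool, had a Pearson's r of 0.093 (0.056 to 0.133 from resampling genes), and those of the Usf1-KO pools 0.241 (0.208 to 0.268). Genes are not independent replicates, so these intervals describe the gene set only.

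Xbp1-KO and Tef-KO had 1 unreplicated pool each and shared the P12+40d WT pool with Nr2f2-KO and Usf1-KO, so part of any fold may come from that pool. In the pool labelled Xbp1-KO, unfolded protein response genes, many of them XBP1 targets, had a median log2 of -0.29 (5 of 20 higher, counting interval -0.311 to -0.27, percentile 0). It fell further in Nr2f2-KO at P12+40d (-0.623, but 0.308 at P60+14d) and Tef-KO, so this is not particular to Xbp1-KO. Fatty acid synthesis genes were lower (0 of 12 higher, median log2 -1.08, percentile 0), and so were cholesterol synthesis genes (0 of 18, median log2 -0.39). Of 23 cell cycle genes, some reaching 1 CPM only through Xbp1-KO, 20 were higher (median log2 1.45). So were all 12 interferon genes (median log2 0.91), both at percentile 100. Single cells held 95.7% of Rsad2 (60.99-fold) and 81.4% of Ifit3 counts (24.4-fold).

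In the pool labelled Tef-KO, Cyp4a14, a fatty acid hydroxylase, stood at 860 against 7.64 CPM (112.6-fold, from 88168 and 1053 counts), the sulfotransferase gene Sult2a2, with no count in WT, was at least 124.2-fold higher, and Cyp4a10 stood at 913 against 25.3 CPM (36.1-fold, 34.9 to 37.3). Fatty acid oxidation genes were higher (17 of 20, median log2 0.62, percentile 100) and fatty acid synthesis genes lower (2 of 12 higher, median log2 -0.68). The clock list had a median log2 of 0.54 (10 of 18 higher, counting interval 0.497 to 0.584, percentile 100), and Dbp, a clock output factor related to Tef, stood at 3.55-fold. Unfolded protein response genes (0 of 20 higher, median log2 -0.74) and acute phase genes (3 of 14, median log2 -0.72) were lower, and interferon genes (11 of 12, median log2 1.00) and periportal genes (22 of 28, median log2 0.77) higher, each at percentile 0 or 100. Igf2, with no count in WT, was at least 86.1-fold higher, and H19, with 2 counts in WT, differed 225.3-fold (61.9 to 1868). Against the same WT pool, Igf2 was at least 131.1-fold and Sult2a2 at least 192.9-fold higher in Nr2f2-KO at P12+40d, where H19 differed 375.7-fold (103.6 to 3108).

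Bulk libraries were made to see whether the surface proteins CD324 and CD73 mark hepatocytes of the portal (PV) and central (CV) zones. The PV cells were sorted on CD324 and the CV cells on CD73, and the sort of the ML cells is given only by that label. The pericentral genes separated CV from PV cells by large factors: Cyp2e1 (chromosome 7, 140763739 to 140774987, plus strand, GRCm38) stood at 25140 ± 1273 CPM in CV and 1816 ± 886 CPM in PV (log2 3.79 ± 0.24, edgeR adjusted p = 4.23e-08, n = 2 libraries each). Oat, an ornithine-metabolising enzyme, rose from 18.8 ± 20.2 in PV to 1818 ± 114.6 CPM in CV (log2 6.68 ± 0.63, edgeR adjusted p = 2.34e-06, n = 2 libraries each), and Slc1a2 (chromosome 2, 102658659 to 102790784, plus strand) from 0.0386 to 293.1 CPM (log2 12.96 ± 0.94). All 30 pericentral genes were called higher in CV, and 30 adjusted over the list alone (median log2 4.01; camera adjusted p = 1.5e-63, but adjusted p = 0.383 with an estimated correlation). All 28 periportal genes were called lower, and 28 adjusted over the list alone (median log2 -3.01; camera adjusted p = 3.3e-118, but adjusted p = 0.196 with an estimated correlation). These included Sds (log2 -6.00 ± 0.13), Hal (log2 -4.70 ± 0.09), Ctsc (log2 -5.00 ± 0.09) and Cyp2f2 (chromosome 7, 27119909 to 27133660, plus strand; log2 -4.66 ± 0.18). The sort markers themselves differed, which is not a finding: Nt5e, which encodes CD73, stood at 6.64 CPM in CV and 0.101 CPM in PV, and Cdh1, which encodes CD324, at 0.581 and 14.5 CPM. Nt5e is 1 of the 30 pericentral genes and Cdh1 1 of the 28 periportal genes, here and in the comparisons with ML.

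Metabolic groups divided along the same axis. Drug-metabolising enzymes held 17 higher and 5 lower of 27 in CV (17 and 7 adjusted over the list alone; camera adjusted p = 9.76e-10, but adjusted p = 0.494 with an estimated correlation), and bile acid genes 10 and 6 of 17 (3.28e-05, but adjusted p = 0.578). Fatty acid oxidation genes held 11 and 5 of 20 (3.44e-03, but adjusted p = 0.548). Cyp7a1 rose from 51.2 to 368 CPM (log2 2.85 ± 0.09) and the cytosolic thioesterase Acot1 15.1-fold (log2 3.92 ± 0.15). Urea cycle genes (1 higher and 6 lower of 10; camera adjusted p = 1.16e-09, but adjusted p = 0.374 with an estimated correlation), gluconeogenesis and glycolysis genes (0 and 9 of 14; 8.02e-08, but adjusted p = 0.383) and plasma proteins (3 and 23 of 26; 4.83e-12, but adjusted p = 0.399) lay lower in CV. Arg1, the final enzyme of the urea cycle, fell from 4110 to 1310 CPM (log2 -1.65 ± 0.04) and Fbp1 of gluconeogenesis 2.75-fold (log2 -1.46 ± 0.04). Alb fell from 91330 ± 608 to 26360 ± 1054 CPM (log2 -1.79 ± 0.02, edgeR adjusted p = 1.53e-14, n = 2 libraries each). Usf1 fell from 37.02 to 7.03 ± 0.178 CPM (log2 -2.40 ± 0.12, edgeR adjusted p = 4.23e-09), Xbp1 had a log2 of -0.34 ± 0.06 (0.000517), and Tef (0.25 ± 0.09, 0.0632) and Nr2f2 (0.16 ± 0.19, 0.591) did not pass. Markers of other liver cells were higher in CV beside these groups: 9 higher and 1 lower stellate markers (camera adjusted p = 2.69e-19, but adjusted p = 0.435 with an estimated correlation), 9 and 0 macrophage (2.46e-05, but adjusted p = 0.581) and 9 and 0 endothelial markers (5.44e-04, but adjusted p = 0.645). Dcn, a fibroblast and stellate cell proteoglycan, stood at 62.6 ± 8.93 against 0.0234 CPM, Stab2 of sinusoidal endothelium at 14.2 against 2.01 CPM and the macrophage gene Lyz2 at 5.58 ± 5.47 against 0 CPM. In contrast, 4 of 5 cholangiocyte markers were lower (4.29e-05, but adjusted p = 0.484). In all, 1653 genes were called higher and 1528 lower in CV than PV of 10984 (edgeR quasi-likelihood, Benjamini-Hochberg).

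CV cells differed from ML cells in much the same lists, and both comparisons used the same CV libraries. Glul rose from 30.9 ± 14.3 in ML to 555 ± 10.5 CPM in CV (log2 4.16 ± 0.21, edgeR adjusted p = 6.06e-09, n = 2 libraries each), Cyp2e1 4.46-fold (log2 2.16 ± 0.23) and the fatty acid receptor Cd36 29.1-fold (log2 4.87 ± 0.17). Hal fell from 556 to 26.95 CPM (log2 -4.37 ± 0.09), and Usf1 fell 4.01-fold. Of 30 pericentral genes, 29 were higher (30 adjusted over the list alone; camera adjusted p = 1.07e-52, but adjusted p = 0.383 with an estimated correlation), and of 28 periportal genes, 27 were lower (28 adjusted over the list alone; 6.02e-93, but adjusted p = 0.196). Stellate markers held 9 higher and 1 lower (camera adjusted p = 3.77e-19, but adjusted p = 0.374 with an estimated correlation), with Dcn 108.9-fold higher. In all, 1250 genes were called higher and 1161 lower in CV than ML.

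PV and ML cells lay closer together. Cyp2e1 fell from 5638 CPM in ML to 1816 CPM in PV (log2 -1.64 ± 0.22, edgeR adjusted p = 0.00147, n = 2 libraries each), the chemokine-like gene Lect2 3.41-fold (log2 -1.77 ± 0.21) and Cyp1a2, which metabolises caffeine, by a log2 of -1.38 ± 0.15. In PV, Sds (log2 0.70 ± 0.08), Ctsc (log2 0.73 ± 0.06) and Aldh1b1 (log2 0.93 ± 0.11) rose. Of 30 pericentral genes, 11 were lower (20 adjusted over the list alone; camera adjusted p = 3.65e-34, but adjusted p = 0.435 with an estimated correlation), and of 28 periportal genes, 8 were higher (19 adjusted over the list alone; 1.3e-21, but adjusted p = 0.374). Plasma proteins held 11 higher of 26 (18 adjusted over the list alone; camera adjusted p = 0.000284, but adjusted p = 0.494 with an estimated correlation), and cholangiocyte markers had a median log2 of 0.11 and a mean of -0.08 (0.0085, but adjusted p = 0.494). In all, 95 genes were called higher and 67 lower, 1 and 21 of them at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). These were 1.47% of the 10984 genes tested. The share was 2.40% with DESeq2, 3.36% without a low-count filter, 0.71% without ML 1, 0.838% without PV 2, 2.38% without CV 1 and 2.39% without CV 2. The balance of directions turned without PV 1 (75 higher and 85 lower) and without ML 2 (47 higher and 61 lower).

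**Figure D4:**
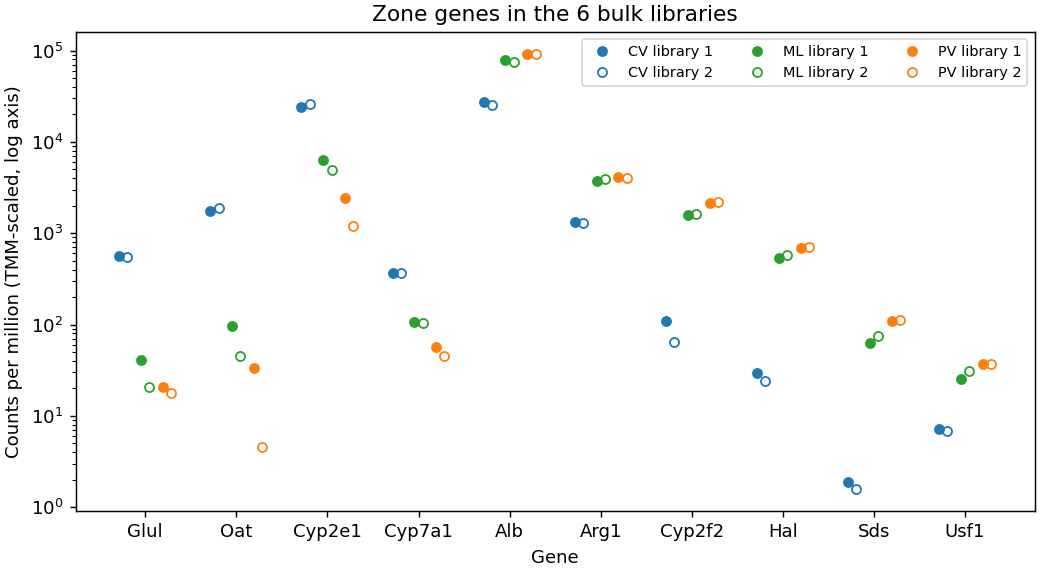
CPM (log axis) of 10 genes in the 6 bulk libraries, 1 point per library, coloured by sort. Glul, Oat, Cyp2e1 and Cyp7a1 are highest in CV, where Cyp2e1 has a mean of 25140 CPM, and Alb, Arg1, Cyp2f2, Hal, Sds and Usf1 are lowest there.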

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

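The tests of the named target, of an acute phase, of other cells in the CV libraries, of a lower hepatocyte share and of diluted RNA in the 2N pool were chosen only after the result was seen, and those of strain haplotypes, of depth and of lobule position were written down first.

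The first pattern weighed is a likeness of knockout pools with different targets: the log2 folds of Nr2f2-KO at P60+14d and Usf1-KO at P12+40d had a Pearson's r of 0.465 across 16183 genes, which are not independent replicates (0.428 to 0.504 from resampling genes). The other 5 pairs with different targets and stages had r of 0.145, 0.115, 0.084, 0.058 and -0.07, and the same-target pairs 0.093 and 0.241. With a median of 0.0995 over the 6 different-target pairs, these values leave the named target open as the main source of the differences. An acute phase state of the animals behind single pools cannot be told apart from the labels: the acute phase list lay above the middle 95% of random lists in 4 of 6 pools, where the idea in its sharpest form needs the pools of that pair alone, and the labels name no animal. Strain haplotypes also stay open: 0 of 6 pools had more neighbouring genes with 8-fold differences than the middle 95% of random draws, a result that met the bound set beforehand for rejecting them, but that bound was set aside after the result because the pools held only 10 to 34 such genes and random draws had a median of 0 neighbours in every pool.

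The second pattern is the higher level of other cell markers in the CV libraries, where 27 of 28 called endothelial, macrophage and stellate markers were higher than in PV and Dcn, the most abundant of the 27, reached 62.6 CPM against 0.0234 CPM. Their level in CV, as CPM of the total, was a median of 12.02 times the highest level in the 4 P60 pools of single hepatocytes (or that of 3 counts where higher), from 0.928 for Egfl7 to 66.1 for Bgn, with 4 of 27 under 3 times. This is consistent with RNA from such cells in the sort for most of these markers, but bulk and single cells were processed with different methods and the pools mix zones, so pericentral hepatocytes with such transcripts were not excluded. A lower hepatocyte share that raises every other cell type alike stays open: 4 of 4 called cholangiocyte markers were lower in CV, but 0 of them stood under 1 CPM in the unsorted P60 cell pool, so their level in hepatocytes would hide a small share. CD73 was the sort marker of these libraries, and no gate against such cells is given in the sources used here.

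The third pattern is the pericentral lean of the 8N and 4N pools against the 2N pool. The 2N cells were no shallower (median counts 149666, 8N 143795), so thinning (pericentral median log2 1.7, 1.51 to 1.79) was no test. RNA of other cell types diluting that of hepatocytes in the 2N pool is argued against by the periportal median, which lay at -0.875 (-0.905 to -0.839) and not above 0, although erythroid markers were higher in the 2N pool as well (median log2 -1.757 for 8N against 2N). A different position in the lobule of the sorted classes remains, as a hypothesis: the 8N against 2N folds had a Pearson's r of 0.381 with the CV against PV folds across 8108 genes, and 0.53 across 2682 genes called in bulk. With 1 pool per class, the animals and the sort may differ as well, and no replicate bears on this.

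Of the groups of 4 pools tested for a pool far from the other 3, 22 (12.1%) had one, where chance gives about 1 in 20 for values without a trend. That rate does not hold here, because the genes were named for changes between windows and levels change with age within a window. These levels are CPM of the pool's total without TMM. At P3, Fgg stood at 6942 CPM (others 10100 to 10650), Usf1 at 252.3 CPM (15.7 to 33.1) and Saa1 at 8.68 CPM (0.211 to 1.42). At E17.5, S100a8 stood at 398 CPM (0.496 to 14.7). At P6, Ggt1 stood at 3.21 CPM (0.0847 to 0.225) and Dlk1 at 2.08 CPM (0 to 0.315). At P15, the last pool of the middle window, Ces3b stood at 1.91 CPM (0.385 to 0.599), Mug2 at 8.98 CPM (0.347 to 1.46), Aldh1a1 at 35.3 CPM (1.99 to 5.69), Mfsd2a at 10.8 CPM (0.0433 to 0.42), Thrsp at 242.8 CPM (4.2 to 10.5) and H19 at 616 CPM (2196 to 2468). At P18, the first pool of the late window, H19 stood at 387.5 CPM (1.18 to 31.3), Psat1 at 6.86 CPM (0.392 to 1.41) and Hadhb at 394 CPM (236.4 to 254.8). At P60, Mup3 stood at 10150 CPM (59.2 to 1393), Mup20 at 6859 CPM (17.2 to 432.6) and Ces3b at 364 CPM (10.5 to 46.8). In nuclei, Slc1a2 stood at 474 CPM in the P60 2N pool (0.704 to 43.9) and 290.8 CPM in the P60 4N pool (0 to 6.98), Alb at 15200 CPM in the P0 2N pool (6508 to 7974) and Usf1 at 37.8 CPM in the P9 2N pool (9.23 to 13.6).

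Some lists had medians of opposite sign at the 2 knockout stages, and these differences were not tested. In Nr2f2-KO against WT the median log2 at P12+40d and P60+14d was -0.815 and 0.668 for cholesterol synthesis, 0.523 and -0.64 for fatty acid oxidation, -0.623 and 0.308 for the unfolded protein response, -0.226 and 1.937 for acute phase and 0.596 and -1.556 for endothelial markers. In Usf1-KO against WT it was 0.615 and -0.569 for erythroid and 0.67 and -0.563 for endothelial markers.

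Spike-ins, which no comparison used, gave a ratio of gene to ERCC counts in each pool, and its order followed DNA content in some pools only. The median cell held 59.3 gene counts per ERCC count at 2N, 122.9 at 4N and 127.5 at 8N, against 284.6 in the unsorted P60 pool. From E17.5 to P30 the unsorted pools had 57.8, 53.6, 174.8, 105.9, 96.3, 47.9, 40.2, 58.7, 105.4, 113.1 and 319.7. The median nucleus held 7.37 in 1x2N, 8.39 in 2x2N, 16.5 in 1x4N and 17.2 in 2x4N. In the 2N and 4N nuclei it held 7.23 and 10.25 at P0, 37.5 and 28.3 at P9, 62.2 and 14.3 at P18 and 104.3 and 195.1 at P60.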

How the results depend on the processing

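The models without embryonic pools, with only the P18 and P60 nuclei, with a minimum of 5000 genes, with ploidy-sorted cells in place of the P60 pool and without Yam1 and RP23-8J15 models were chosen after the data were seen. Among the alternative values for counts of calls and single results, 14 were smaller by more than 1.5 times or lost the threshold, 18 were larger by as much, 3 moved and 0 reversed. Counts of calls are given as a percent of the genes tested in the model reported. Of 4803 values for named genes, 4498 were counted as unchanged and 0 as reversed. In tested comparisons, a change of sign counted as a reversal only where the gene passed in either fit. Sign changes of genes that passed in neither fit are therefore among the unchanged. In untested pairs, unchanged means within the counting interval of the reported fold. Settings that removed no cell are among these values too. The share of late against early calls stayed between 31.7% and 42.2% when each age was left out and within 1.5 times under every setting tried. Leaving out each age gave 1.62% to 23.4% for middle against early and 3.24% to 16.3% for late against middle, against 13.3% and 12.2% with all. DESeq2's test gave 21.3% and 20.5%, and leaving out both embryonic pools gave 0.0621% for middle against early. The embryonic pools are also the only age pools in which most cells held Xist, so age and sex cannot be told apart there. No other boundary between windows was tried, and the cause was not tested.

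In nuclei, 0 genes were called with edgeR (361 at an unadjusted p under 0.05), 0.23% with no low-count filter, 0.207% with DESeq2, 0.00768% (1 gene) with every nucleus thinned, 0.131% with only the P18 and P60 pairs and 0 to 0.223% leaving out each pair. For Nr2f2-KO, 0 genes were called with edgeR, 0.976% with DESeq2 and 0 to 0.494% leaving out each pool, and for Usf1-KO 0, 1.02% and 0 to 0.161%. A group left with 1 pool is assumed to vary like the others in these models. In bulk, leaving out each library gave 20.9% to 28.8% for CV against PV, 15.1% to 23.04% for CV against ML and 0.71% to 2.39% for PV against ML, which had 3.36% with no filter and 2.4% with DESeq2. The cause was not tested.

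Some list medians changed sign. Without the embryonic pools the periportal median of middle against early was -0.039. In Nr2f2-KO against WT, the endothelial median was 0.062 with cells thinned and -2.685 to 0.446 leaving out each pool, above 0 without WT (0.446) or Nr2f2-KO at P60+14d (0.18). Leaving out each pool also gave -0.095 to 1.777 for female-biased genes, below 0 without WT (-0.043) or Nr2f2-KO at P12+40d, -0.324 to 1.632 for fetal and -0.158 to 2.09 for cell cycle genes, both below 0 without Nr2f2-KO at P12+40d, and -0.898 to 2.631 for acute phase genes, below 0 without Nr2f2-KO at P60+14d. In Usf1-KO against WT the ranges were -0.026 to 0.727 for the unfolded protein response and -0.469 to 2.893 for acute phase genes, below 0 without Usf1-KO at P12+40d. For PV against ML the stellate median was -3.086 to 0, with 0 without ML 1, and the interferon median -0.001 to 0.486, below 0 without ML 2. The cause was not tested. Thinning moved the pericentral median of 2x2N against 1x2N nuclei to 0.117, the unfolded protein response median of Xbp1-KO to -0.264 and the correlation of Usf1-KO folds over stages to 0.267.

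Deviations of same-numbered bulk libraries had r of 0.053, 0.112 and 0.092, and 2 libraries per sort cannot show if numbers mark animals. With that number as a block, CV against PV had 28.3%, CV against ML 21.4% and PV against ML 1.502%, and with no block the nuclei had 0. The planned minima of 1000 and 500 genes removed no cell and test nothing. Depth limits the P0 and P9 4N nuclei most, with 12 and 21 nuclei.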

Other observations

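The age test written down first concerns the lobule, and the counts of other splits of the pools were tests chosen only after the result was seen.

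Usf1 was highest at P6 in the age series, given here as CPM of each pool's total without TMM. It stood at 23.3 CPM at E17.5, 15.7 at E19.5 and 33.1 at P0, reached 252.3 at P3 and 551.5 at P6, and then stood at 468, 361.6, 210, 155.4, 76.5, 86.6 and 119.5 CPM from P9 to P60. In bulk its level was 5.27-fold lower in CV than in PV. Male-biased genes also divided along the lobule: Mup20 fell from 15120 CPM in PV to 1726 CPM in CV (log2 -3.13 ± 0.09, edgeR adjusted p = 1.17e-11, n = 2 libraries each), while Elovl3 rose 5.49-fold (log2 2.46 ± 0.09), and the list held 9 higher and 4 lower in CV (camera adjusted p = 0.0116, but adjusted p = 0.613 with an estimated correlation). Acute phase genes were mostly lower in CV, with 1 higher and 10 lower (camera adjusted p = 9.51e-07, but adjusted p = 0.395 with an estimated correlation), including Apcs (log2 -1.45 ± 0.06) and Itih4 (log2 -1.21 ± 0.05).

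Single knockout pools differed strongly from their WT pool in a few gene groups, without a replicate check. In Usf1-KO at P12+40d, Saa3 differed 176.1-fold (256503 and 3684 counts), all 14 acute phase genes were higher (median log2 2.22) and all 8 macrophage markers were too (median log2 1.54), where the median of all genes was -0.28. In Usf1-KO at P60+14d, Moxd1 (151.8-fold, 82.3 to 317.3), Hebp2 (73.95-fold, 37.3 to 172.2) and the chemokine Cxcl14 (39.8-fold, 29.3 to 55.5) had the largest folds among the higher genes, by the interval bound nearest 1, and the cholangiocyte marker Spp1 (14.7-fold, 13.6 to 16.0) and Tff3 (15.02-fold, 14.02 to 16.1) were also among the 10 largest of these. Among the lower genes, H19 and Igf2 had no count and were at least 158.6-fold and 83.2-fold lower. In Nr2f2-KO, Cyp4a14 was 35.7-fold higher (33.55 to 37.96) at P12+40d, against the WT pool that Tef-KO shares, and its relative Cyp4a10 stood at 0.0578-fold of WT at P60+14d. In 2x2N against 1x2N nuclei, Saa3 stood at 0.0261-fold, Lcn2 at 0.15-fold and Saa1 at 0.166-fold, with 89.9% of the Saa3 counts in 1 nucleus.

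A hypothesis was that genes that rise with age lean toward the pericentral end of the lobule. Among 1551 genes called higher in CV than PV, 686 rose from the early to the late window (44.2%) and 8.1% fell, and among 1495 genes higher in PV, 20.8% rose and 20.7% fell. The shares that rose differed by 23.4 percentage points, above the 10 points set beforehand, which is in line with such a lean in these pools. Genes are not independent, and the RNA of other cells in the CV libraries may enter both shares.

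Other splits of the pools were counted for the models with at least 3 pools per group. For middle against early, 1 of 35 splits, the real one, gave 1713 calls, and the highest of the others gave 1. For late against middle, 1 of 35 splits, the real one, gave 1571 and the highest other 0. For late against early, 1 of 35 gave 5112 and the highest other 1. The pools follow age order, so anything that runs with that order makes the real split stand out. All other splits mix the windows. The counts therefore cannot exclude chance differences between single pools. For 4N against 2N nuclei, the 8 splits are too few for a share under 0.05, 8 of 8 gave at least the real count of 0, and the highest other was 0.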
